A study of Homo sapiens with 2 samples.

How the data were processed

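Total RNA from 2 stable transfectants of the human breast cancer line MDA-MB 231 was measured on Affymetrix GeneChip expression arrays, 1 array for cells carrying the S100A7 gene in the plasmid pIRES2-EGFP and 1 array for cells carrying the plasmid without it. Per the labels' protocols, the growth medium was DMEM supplemented with bovine serum (10%) and antibiotics (1%), and cultures were kept at 37 °C in 5% CO2, RNA was extracted with Trizol, and 2 µg of RNA was turned into biotin-labelled cRNA. The confluence at harvest is given in the label of the vector sample and not in that of the S100A7 sample, whose description holds in its place a line about early embryos that does not describe a cell line and was not used.

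The deposited values are 1 intensity per probe set on a linear scale, made with the MAS5 algorithm per the submitters' processing notes. The MAS5 version, the scaling target and any detection calls are not given in the sources used here. Over the 54675 probe sets of each array, the mean after trimming 2% at each end was 500.1 on both arrays, so the arrays were taken as already scaled to each other and were used as deposited. The median intensity was 71.2 on the vector array and 69.2 on the S100A7 array. Columns of values left unused numbered 0.

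Probe sets were named through the platform's annotation table, which paired 41097 of them with 1 gene, 1801 with several and 11721 with none listed; 62 were control probe sets. Of the probe sets with 1 gene, 41043 were matched by Entrez identifier to a table of human genes on assembly GRCh38.p14, used for current symbols and for the order of genes along chromosomes. The probe sets with 1 gene, other than controls, covered 19775 genes. Probe sets listing several genes or none were kept out of the gene counts and gene lists.

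Each array's 50th percentile of probe sets other than controls, 71.0 for the vector array and 69.0 for the S100A7 array, served as a floor in place of a detection call. A probe set was measured when it reached the floor on at least 1 array, lower values were raised to the floor, and a fold change with 1 side at the floor is a lower bound, written as at least that size. This left 24438 probe sets for 12688 genes, of which 6223 had 1 measured probe set and 6465 had 2 or more. Each gene was represented by its brightest measured probe set, and the log2 ratio of the S100A7 array over the vector array was taken.

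With 1 array per group there were no replicates, no statistical test and no p-value, and genes were counted by size, at least 2-fold in either direction. The number of arrays limits the precision: neither the spread between cultures nor that between separately selected stable lines was measured. As a partial substitute, the pooled standard deviation of log2 ratios between probe sets of the same gene was computed, along with the log2 ratios of the RNA controls added to the samples and the 3' over 5' intensity ratios of the ACTB and GAPDH controls.

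The lists, 28 in number, were fixed before the data were examined, and chemokines and cytokines, NF-kB genes and interferon-stimulated genes were the 3 primary ones. Each list was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, drawn within 20 bins of mean log2 intensity. A percentile under 2.5 or over 97.5 was read as outside the central 95% of random lists, which describes these arrays only. Genes were named by a rule that was also fixed beforehand: S100A7 and S100A7A; the 8 genes with the highest and the 8 with the lowest log2 ratio among those with at least 2 measured probe sets all at least 1.5-fold apart in the same direction; the 4 highest and 4 lowest of the other genes; and from each list up to 3 members at least 2-fold higher and 3 at least 2-fold lower. Provisional symbols were counted and not named. Any other gene named in the text was chosen after its values were seen.

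The alternatives fixed beforehand were median centring and quantile normalization of the arrays, floors at the 30th and 70th percentile, no floor, a pseudocount of 32 in place of the floor, the median over a gene's probe sets, probe sets without the suffixes _x_at and _s_at (which can match several transcripts), thresholds of 1.5-fold and 3-fold, agreement between probe sets, no filter on low values, unmatched random lists, list means, and lists without their largest member. Subtracting the median log2 ratio of the 40 nearest measured genes along the chromosome, 20 on each side, was added after the data had been seen.

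The counting and list steps were tested on simulated arrays for this comparison, in which 12246 genes were measured. Of 50 measured genes given a 2-fold change, 50% were called, against 92% of those given a 3-fold change, 96% at 5-fold and 98% at 8-fold, with 0 called in the wrong direction. The 50% at 2-fold was set by construction, because the change equalled the threshold. Among 12018 unchanged genes 61 were called, or 0.508%. The simulated noise had 1 size for all probe sets, the pooled standard deviation between probe sets of the same gene (0.36 on the log2 scale). It held no differences between cultures or stable lines, so 0.508% is not a false-call rate for the real arrays. A list of 30 genes shifted by 0.5 on the log2 scale reached percentile 100, and an unchanged list of 30 genes reached percentile 60.6. Computations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.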

Results

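The data compare the MDA-MB 231 cell line, a highly invasive, estrogen receptor-negative human breast cancer line, after stable transfection with S100A7 or with the empty plasmid, with 1 array for each. S100A7, also called psoriasin, is a small calcium-binding protein best known from inflamed skin. The series asks which genes it regulates, and its title points to inflammatory pathways. Intensities ran from 0.168 to 63370.2 on the vector array and from 0.113 to 53801 on the S100A7 array, and 27307 probe sets reached the floor on each. That number is equal by construction, because the floor was each array's own 50th percentile. There were no replicates, so no difference below has been checked against the spread between cultures.

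The transfected gene was far higher in the S100A7 array. The S100A7 probe set read 11.99 in vector cells, below the floor, and 13232 in S100A7 cells, at least 186-fold higher. S100A7A, its close relative and neighbour on chromosome 1, did not follow it: its 1 measured probe set read 86.9 in vector cells and 79.2 in S100A7 cells.

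Beyond the transgene, the genes with the largest increases included CCDC3 (at least 8.77-fold higher), FERMT3, the integrin activator kindlin-3 (8.54-fold higher), and HSD11B1, the enzyme that makes cortisol from cortisone (8.50-fold higher). The largest decreases were in IL13RA2, a decoy receptor for interleukin-13, whose intensity was 6615 in vector cells and 119 in S100A7 cells (55.8-fold lower), and in FGF13, a fibroblast growth factor that is not secreted (at least 35.7-fold lower). MAGEA6, a cancer-testis antigen, was at least 12.97-fold lower, and HBE1, the embryonic epsilon globin, at least 12.8-fold lower. Each of these genes rested on 1 measured probe set. That of MAGEA6 carries a suffix for probes shared within a gene family, and that of FGF13 the suffix _s_at, which can match several transcripts.

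Among genes whose probe sets agreed, RCSD1 was 4.88-fold higher and COL6A2, a chain of collagen VI, 4.40-fold higher (274 in vector cells and 1203 in S100A7 cells). CXCL8 (interleukin-8, which attracts neutrophils) was 3.74-fold higher, IL11 (a cytokine of the interleukin-6 family) 3.66-fold, the pseudogene CEP192P1 3.47-fold, MYLK (myosin light chain kinase) 3.27-fold, KCTD4 3.26-fold and PXDN (peroxidasin, which cross-links basement membrane collagen) 3.17-fold. In the other direction, FAM133A was at least 8.74-fold lower and NEO1 (neogenin, a receptor for netrins and repulsive guidance molecules) was 8.11-fold lower, at 1242 in vector cells and 153 in S100A7 cells. TMEM132D-AS1 was at least 3.72-fold lower, CENPBD1P 3.18-fold, the deubiquitinase gene OTUD5 3.07-fold (its 3 probe sets from -1.62 to -0.62 on the log2 scale), ZNF542P 3.05-fold, the matricellular protein gene CCN3 2.91-fold and ZNF385B at least 2.70-fold lower. These folds are those of the brightest probe set. Log2 ratios of other probe sets were weaker for genes including RCSD1 (0.87), KCTD4 (0.62), CENPBD1P (-0.84) and CCN3 (-0.69), and stronger for MYLK (2.02) and PXDN (2.09).

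In all, 228 of 12688 measured genes were at least 2-fold higher in the S100A7 array and 286 at least 2-fold lower, while 95.9% lay within 2-fold. Of these folds, 46 of the higher and 80 of the lower ones were lower bounds. Probe sets agreed for 43 of the 110 higher genes and 49 of the 112 lower genes that had at least 2. The median log2 ratio of all measured genes was -0.04, and across the 11242 genes above the floor on both arrays the log2 intensities correlated at Pearson r 0.973, genes not being independent replicates. The standard deviation between probe sets of a gene was 0.36 on the log2 scale over 6465 genes. It was 0.42 in the dimmest 2155 of these genes, 0.35 in the middle 2155 and 0.33 in the brightest 2155. These counts depend on the floor: 679 genes were higher and 979 lower with a floor at the 30th percentile, and 99 and 88 with one at the 70th.

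**Figure D1:**
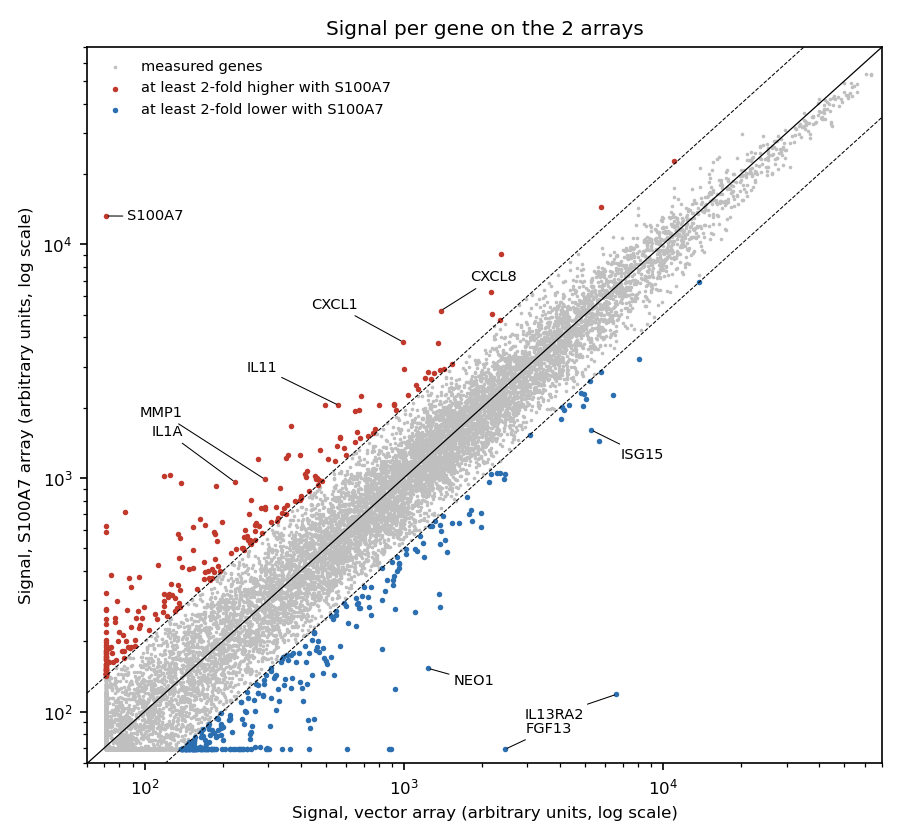
Intensity of each measured gene on the vector array (horizontal) and on the S100A7 array (vertical), in arbitrary units on log scales, with values under the floor raised to it; the solid line marks equal values and the dashed lines a 2-fold difference. The 228 genes at least 2-fold higher with S100A7 are red and the 286 at least 2-fold lower are blue, with S100A7 itself far above the diagonal and IL13RA2 and FGF13 far below it.

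Chemokine and cytokine genes, the first primary list, were higher in the S100A7 array. IL1A, a cytokine that alerts neighbouring tissue, was 4.32-fold higher, and CXCL1, a neutrophil attractant like CXCL8, was 3.86-fold higher, at 991 in vector cells and 3825 in S100A7 cells. CXCL8 read 1392 and 5207, with both of its probe sets higher (log2 ratios 1.64 and 1.90). Their names end in _x_at and _s_at, suffixes that can match several transcripts. IL11 read 559.6 and 2049, and its other probe set was 2.05-fold higher. Of 48 genes listed 27 were measured, 7 of them at least 2-fold higher and 0 at least 2-fold lower, and 20 had a log2 ratio above 0. The 7 also included IL32 (at least 3.33-fold higher), IL7 (at least 2.34-fold) and IL6 (2.02-fold), chosen after their values were seen. The median log2 ratio of the list was 0.46, at percentile 100 among random lists. Not all members shared in this: IL1B had a log2 ratio of 0.10, MIF -0.25 and TGFB1 -0.91, and CCL2, CCL5, CCL20 and TNF were below the floor on both arrays. The increase of IL1A rested on 1 of its 2 measured probe sets, the other having a log2 ratio of -0.02.

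NF-kB target and pathway genes moved in the same direction by smaller amounts. ICAM1, an adhesion molecule for leukocytes, was 2.30-fold higher with its 3 probe sets between 1.02 and 1.25 on the log2 scale. IER3, an early response gene that limits cell death, was 2.07-fold higher at a high level (11012 in vector cells, 22781 in S100A7 cells). RIPK2, a kinase that signals from intracellular pattern receptors, was 2.05-fold lower, with its other probe set at -0.48, and was under 2-fold with median centring. These were the 3 members outside 2-fold among 31 measured of 38 listed, and 22 had a log2 ratio above 0. TNFAIP3, a feedback inhibitor of NF-kB, had a log2 ratio of 0.99, NFKB2 0.85 and NFKBIA 0.66, against -0.29 for NFKB1 and 0.01 for RELB. The other measured probe set was weaker for TNFAIP3 (0.46) and for NFKB2 (0.45). The median was 0.22, at percentile 99.8 among random lists. This call depended on probe sets with shared-transcript suffixes, since without them the median was 0.02 at percentile 67.8. Members read only by such probe sets, ICAM1 and IER3 among them, left the list in that setting, so it did not compare the same genes.

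Interferon-stimulated genes did not move together. ISG15, a ubiquitin-like protein and a typical interferon target, was 3.30-fold lower, at 5293 in vector cells and 1604 in S100A7 cells. SAMD9 was 2.21-fold lower and OASL 2.18-fold lower, with another probe set at -0.22 on the log2 scale for SAMD9 and at -0.66 for OASL, and ISG20, chosen after its value was seen, was 2.11-fold lower. Against these, PSMB9, a subunit of the immunoproteasome, was 2.18-fold higher, the guanylate-binding protein gene GBP2 2.11-fold and PARP14 2.10-fold. Of 48 listed genes 41 were measured, and 34 of them lay within 2-fold. The median log2 ratio was 0.10 and the mean 0.01, with the median at percentile 93.2, inside the central 95% of random lists.

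Antigen presentation genes were higher as a group. NLRC5, a transcriptional activator of MHC class I genes, was 2.52-fold higher and ERAP1, a peptide-trimming protease, 2.49-fold higher, although other probe sets of ERAP1 went as low as -0.39 on the log2 scale. PSMB9 belongs here too, and CD74, the MHC class II invariant chain, was the other of 4 members at least 2-fold higher (log2 ratio at least 1.08, chosen after its value was seen). HLA-DRB1, read by a probe set shared within its family, was 3.77-fold lower, the 1 member at least 2-fold lower. Of 22 listed genes 19 were measured and 16 had a log2 ratio above 0, with HLA-B at 0.35, HLA-C at 0.42 and TAPBP at 0.83. The median was 0.44, at percentile 100. Of the 19, 13 lie on chromosome 6, whose measured genes had a median log2 ratio of 0.24.

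Matrix and adhesion genes were higher in the S100A7 array as well. Among collagens, laminins and integrins, COL6A1 was 3.51-fold higher beside COL6A2, and LAMA5, a laminin chain of basement membranes, was 3.17-fold higher, while TNC (tenascin-C) was 3.15-fold lower. The 6 probe sets of COL6A1 ranged from -0.30 to 1.81. Of 29 measured members among 41 listed, 6 were at least 2-fold higher and 1 lower. The other higher ones were COL5A1 (3.06-fold), COL4A1 (2.30-fold) and LAMC1 (2.16-fold), chosen after their values were seen. The median was 0.34, at percentile 100. For 23 measured mesenchymal genes the median was 0.21, at percentile 99.6, with SNAI2, the repressor Slug, 2.11-fold higher and 0 members at least 2-fold lower. Without probe sets of the shared-transcript suffixes the percentile of that list was 89.2.

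Matrix proteases went both ways. MMP1, the interstitial collagenase, was 3.40-fold higher (291 in vector cells, 988 in S100A7 cells), MMP9, a gelatinase, was 3.33-fold higher (136 and 453), and the lysosomal protease gene CTSD was 2.10-fold higher. ADAMTS6 was 2.83-fold lower, the heparan sulfate-degrading enzyme gene HPSE 2.62-fold and MMP3 (stromelysin-1) 2.04-fold lower. The 3 probe sets of ADAMTS6 ranged up to -0.28, that of HPSE without a shared-transcript suffix was at -0.72, and MMP3 was under 2-fold with median centring. With 3 members higher and 3 lower among 26 measured, the median of proteases and inhibitors was -0.08, at percentile 32.1.

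Genes of the G2/M phase of the cell cycle had a median of 0.19, at percentile 99.9, with 24 of 32 members above 0 and 0 outside 2-fold. NEK2, KIF11 and CCNA2 had log2 ratios of 0.90, 0.80 and 0.78, and FOXM1 -0.45. Genes of the G1/S transition had a median of 0.04 at percentile 80.5, with 0 of 29 outside 2-fold, and reached percentile 99.02 after subtracting the median of chromosomal neighbours. The S100 family list, fixed without S100A7 and holding also the S100P-binding protein gene S100PBP (0.32), had a median of 0.26, at percentile 98.96, and 0 of 11 measured members outside 2-fold, S100A3 at 0.76 and S100A11 at 0.62 being the highest. All 11 lie on chromosome 1, whose median was 0.10, and the percentile was 90.4 after subtracting the median of chromosomal neighbours, 97.0 without shared-transcript probe sets and 97.3 against unmatched random lists.

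The receptors and partners described for S100A7 and its relatives showed a median of -0.08 over 8 measured genes (percentile 39.8), and AGER, the receptor for advanced glycation end products, was below the floor on both arrays. Epidermal differentiation genes had a median of -0.15 and a mean of 0.06 (percentile 17.8, 8 measured), with FLG, the skin barrier protein filaggrin, at least 3.89-fold higher from a vector intensity of 22.4. Immediate-early and AP-1 genes had a median of -0.18 (percentile 3.96), with 20 of 28 below 0, and 7 of 12 alternatives put the list below the central 95% of random lists, at percentiles 0.58 to 2.10. Of its members EGR1 was 2.13-fold lower, on a probe set whose companions ranged to -1.68. Epithelial junction and keratin genes had a median of -0.02 and a mean of 0.08 (percentile 58.6, 24 measured), and the sign of the median turned under median centring. Among them the transcription factor gene ELF3 was 2.17-fold higher, ITGB4 2.13-fold (other probe sets down to 0.31) and KRT7 2.00-fold, while another KRT7 probe set had a log2 ratio of -0.86. ELF3 read 75.6 in vector cells, near the floor of 71.0, and its other probe sets were below the floor on both arrays. Luminal and estrogen receptor genes had a median of 0.03 (percentile 71.0, 12 measured).

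TGF-beta and BMP response genes had a median of 0.10 and a mean of 0.27 (percentile 89.4, 23 measured), and 3 of them were at least 2-fold higher: the inhibitory SMAD7 (3.18-fold) and SMAD6 (at least 2.49-fold), and ID3 (2.19-fold). This list stood above the central 95% of random lists under 3 alternatives, at percentiles 98.8 to 99.96. Beta-catenin target genes had a median of 0.12 (percentile 91.0, 17 measured), with the secreted Wnt antagonist DKK1 2.49-fold higher (5779 in vector cells, 14388 in S100A7 cells) and the hepatocyte growth factor receptor gene MET 2.06-fold lower. Angiogenic factors had a median of 0.04 and a mean of -0.05 (percentile 76.3, 21 measured), and the growth factor gene TGFA was 2.40-fold higher, although its 3 probe sets ranged down to -0.10. Hypoxia and glycolysis genes had a median of 0.06 (percentile 91.6, 28 measured), with ALDOC, an aldolase, 2.15-fold higher; their mean stood at percentile 97.97.

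The unfolded protein and amino acid response had a median of -0.12 (percentile 15.3, 29 measured), with the pseudokinase gene TRIB3 2.25-fold lower. This list stood at percentile 1.19 with the median over probe sets. After subtracting the median of chromosomal neighbours it stood at 80.5, and TRIB3 was under 2-fold. Oxidative stress and NRF2 genes had a median of -0.13 (percentile 19.1, 20 measured), with sulfiredoxin (SRXN1) 2.17-fold lower and AKR1C1 2.11-fold lower. Medians were 0.05 for cholesterol synthesis (percentile 80.9, 22 measured), 0.08 for apoptosis and p53 targets (percentile 85.8, 21 measured), 0.01 with a mean of -0.03 for oxidative phosphorylation (percentile 86.0, 30 measured), -0.16 for ribosomal proteins (percentile 4.30, 26 measured) and -0.14 for reference genes (percentile 17.2, 13 measured), each with 0 members outside 2-fold. The mean of the ribosomal proteins stood at percentile 2.06. Of the 28 lists, 7 lay outside the central 95% of random lists, all 7 above it. Chance would give 1.4 for lists of independent genes, but some lists share members and neighbouring genes moved together. Of these 7, 3 came inside under at least 1 alternative, and 6 of the others came outside.

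**Figure D2:**
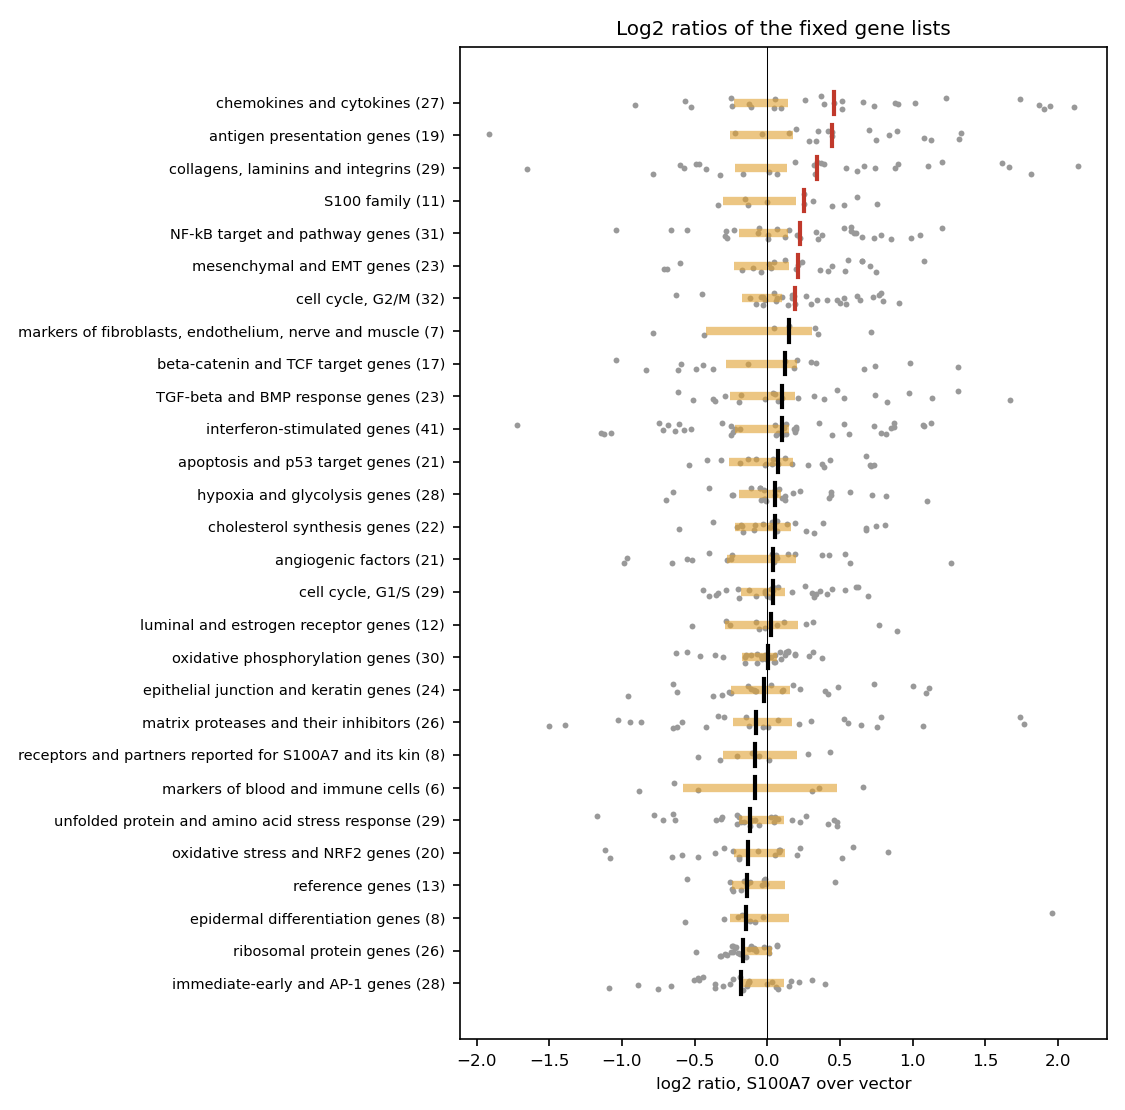
Log2 ratio of the S100A7 array over the vector array (horizontal) for each measured member (grey points) of the 28 lists, with the number of measured members in brackets and points spread vertically for legibility. Vertical ticks mark list medians, red for the 7 lists outside the central 95% of random lists and black for the others, and orange bars span 2 standard deviations on either side of the random lists' median; chemokines and cytokines had the highest median, 0.46.

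RNA quality was similar on both arrays, with 3' over 5' ratios of 1.09 in vector cells and 1.07 in S100A7 cells for ACTB, and of 0.718 and 0.801 for GAPDH. The 18 hybridisation control probe sets had a median log2 ratio of -0.01 with a standard deviation of 0.10, and the 42 probe sets of all added RNA controls had a median of -0.06. Markers of blood and immune cells had a median of -0.08 (percentile 45.4, 6 measured), and the leukocyte genes PTPRC (27.2 in vector cells, 50.1 in S100A7 cells), TYROBP (6.35, 10.6) and LYZ (32.03, 7.39) were below the floor on both arrays, whereas LAPTM5 read 2563 and 4048. Markers of fibroblasts, endothelium, nerve and muscle had a median of 0.15 (percentile 90.0, 7 measured), with 0 outside 2-fold.

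Log2 ratios also differed by chromosome. The bootstrap intervals treat genes as independent, although neighbouring genes moved together, so they are likely too narrow and hold no spread between cultures. Genes of chromosome 18 had a median of 0.35 (95% bootstrap interval over genes 0.25 to 0.42, 179 genes) and those of chromosome 6 of 0.24 (0.21 to 0.31, 664 genes). Genes of chromosome 15, where NEO1 lies, had a median of -0.33 (-0.37 to -0.30, 420 genes), and those of chromosome 7 of -0.30 (-0.35 to -0.27, 576 genes), with 29 genes at least 2-fold lower and 2 higher. Chromosome X, which carries IL13RA2, FGF13, MAGEA6, FAM133A and OTUD5, had 26 genes at least 2-fold lower and 1 higher, at a median of -0.16 over 394 genes.

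**Figure D3:**
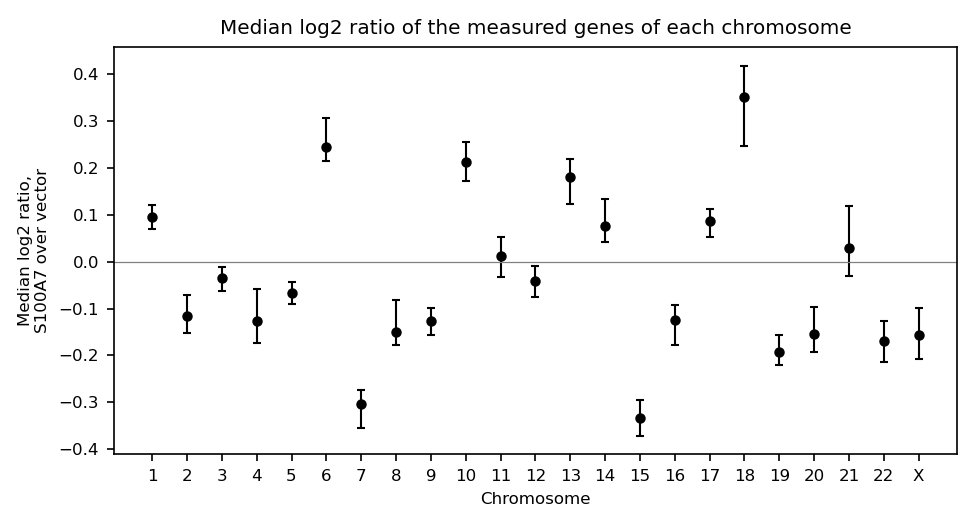
Median log2 ratio of the S100A7 array over the vector array (vertical) for the measured genes of each chromosome (horizontal), with 95% bootstrap intervals over genes as bars. The intervals treat genes as independent and do not measure the spread between cultures. Chromosome 18 lies highest, at 0.35, and chromosome 15 lowest, at -0.33.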

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

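The test of scaling, the test of neighbouring genes around the chemokines and cytokines, and the test of shared probes were chosen after the results they bear on had been seen, as was the list of cancer-testis genes, after IL13RA2, MAGEA6 and FAM133A had been seen among the largest decreases.

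Probe sets outside the gene comparisons also differed between the arrays. Probe sets listing several genes were at least 2-fold higher in the S100A7 array in 32 of 1174 measured cases and lower in 41. Those with no gene listed were higher in 86 of 3848 and lower in 50. The largest increase among probe sets listing several genes was a log2 ratio of 3.78, from 544 in vector cells to 7466 in S100A7 cells, and the next was 11.7-fold, from 1887 to 22132. The genes of these probe sets are not named here, because each lists more than 1 gene.

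The chemokine and cytokine genes stood out among the primary lists, with CXCL1 and CXCL8 each over 3-fold higher, as was 1 of 2 probe sets of IL11 and of IL1A. The other probe set of IL11 was 2.05-fold higher, and that of IL1A had a log2 ratio of -0.02. A uniform difference in scaling was argued against, since it would move all genes alike. The median of the list was 0.46 as deposited, against -0.04 for all measured genes. Its value under median centring follows from these 2 medians by construction and adds no evidence. With quantile normalization, which also allows scaling to depend on intensity, the median was 0.45. A copy-number difference at the genes was argued against as the cause of the shift of the list, since the 432 genes next to its 27 measured members had a median log2 ratio of -0.033. An effect of S100A7, a difference between stable lines unrelated to S100A7, and a difference between cultures or in array handling cannot be told apart, because there was 1 array per group. The labels do not say whether each sample was a single clone or a pool of stable cells. They give the confluence at harvest for the vector sample only. All of these explanations stay open.

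Cancer-testis genes, normally silent outside the germ line and placenta, were lower in the S100A7 array, with 8 of 13 measured genes of 74 listed at least 2-fold lower and 0 higher; without the 3 genes that prompted the list, 5 of 10 were lower and the median was -0.83, at percentile 0. These genes lie on chromosome X. Loss of a whole X chromosome in all cells was argued against by the other 381 X-linked genes, whose median was -0.14 (95% bootstrap interval -0.19 to -0.09). Its loss in a part of the cells stays open. If such a loss lowered X-linked genes alike, it could account for a small part of the decrease only, as -0.14 is far from -0.83. Bootstrap intervals over genes or probe sets treat them as independent, although neighbouring genes moved together. They are likely too narrow and hold no spread between cultures. Probes shared between family members stay open as the cause of part of the decrease: without the 3 prompting genes, the 6 probe sets lacking the suffixes for shared transcripts had a median of -0.53 (95% bootstrap interval -1.11 to -0.15), with 2 of them at least 2-fold lower. Loss of a part of chromosome X stays open as the cause of part of the decrease, as the 40 genes from UXT to GPR173 had a median of -0.70. Cancer-testis genes were not left out of that stretch, and which of the 13 lie in it was not examined. Its loss could not account for listed genes that lie elsewhere on chromosome X. An effect of S100A7 and the selection of a line in which these genes were silenced also stay open and were not tested.

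Neighbouring genes tended to move together along the chromosomes, with a Spearman correlation of 0.22 between the log2 ratios of adjacent measured genes, above the highest of 1000 shuffles of gene order (0.02). Co-regulation or shared probes of immediate neighbours were argued against as the whole cause, since genes 20 apart still correlated at 0.18 (highest shuffle 0.03). Local gene density was argued against, since the correlation at that distance was 0.17 after centring on density (highest shuffle 0.03), while base composition itself was not measured. Copy-number differences between the lines and regional regulation over longer distances both stay open, since the correlation of 0.22 is the pattern itself and no measurement of DNA copy number was analysed here.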

How the results depend on the processing

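Centring on chromosomal neighbours was the alternative chosen after the results had been seen. No paired analysis was possible because each group had 1 array and no test was run. For the genes at least 2-fold higher and lower (228 and 286), counts were 679 and 979 with a floor at the 30th percentile, 99 and 88 at the 70th, 493 and 660 with no floor, 1030 and 1275 at a 1.5-fold threshold, 47 and 55 at 3-fold, 43 and 49 for agreeing probe sets, and 1911 and 2387 with no filter and no floor. They stayed within 1.5 times of 228 and 286 under median centring, quantile normalization, the pseudocount, the median over probe sets, the removal of _x_at and _s_at probe sets, and neighbour centring, which shared 168 and 179 of those genes. Median centring shared 228 and 247 of them, quantile normalization 223 and 281, and the pseudocount 170 and 202. The median over probe sets shared 155 and 216, and the removal of _x_at and _s_at probe sets 165 and 201. The balance of the counts turned, with 267 higher and 247 lower under median centring, 246 and 217 after neighbour centring and 228 and 227 without _x_at and _s_at probe sets, as it did at the 70th percentile floor. The log2 ratio of S100A7, a lower bound of 7.54, was 8.96 and 5.55 with floors at the 30th and 70th percentile, 10.11 with no floor and 8.24 with the pseudocount. The chemokine and cytokine median was 0.76 with a floor at the 70th percentile and 0.55 as a mean, and lay between 0.42 and 0.52 under the other alternatives, at percentile 100 throughout. The NF-kB median was 0.33 with no floor, 0.32 after neighbour centring, and 0.015 at percentile 67.8 without _x_at and _s_at probe sets. In that last setting 9940 of the 12688 genes had a value, so the members of lists also changed. CXCL8, ICAM1 and IER3 were among the genes without a value there. The interferon-stimulated median stayed between 0.01 and 0.14 and inside the central 95% of random lists. Without _x_at and _s_at probe sets the log2 ratio was -0.020 for IL1A, -0.86 for KRT7 and -0.39 for ERAP1. The cause of these shifts was not tested, except that the floor and the threshold set by construction which folds can be counted. Of the 63 named genes at least 2-fold apart, 63 kept that size and direction under quantile normalization and 61 under median centring (not RIPK2 and MMP3). With the 70th percentile floor 43 of 55 did (not CENPBD1P, ZNF542P, CCN3, SAMD9, OASL, AKR1C1, PARP14, GBP2, ITGB4, NLRC5, SMAD7 and MMP9), and with the pseudocount 56 (not AKR1C1, MMP3, KRT7, PARP14, GBP2, ITGB4 and ELF3). With the median over probe sets 53 did (not OTUD5, ZNF385B, SAMD9, OASL, RIPK2, KRT7, GBP2, ITGB4, TGFA and ERAP1), and without _x_at and _s_at probe sets 42 of 48 (not HPSE, OASL, RIPK2, KRT7, ERAP1 and IL1A). After neighbour centring 50 did (not OTUD5, TRIB3, SAMD9, SRXN1, MET, RIPK2, MMP3, IER3, SNAI2, ITGB4, PSMB9, ID3 and DKK1). Lists of antigen presentation, collagens and G2/M genes stayed above the central 95% of random lists under every alternative run. Of the other lists, 3 outside it as reported came inside under at least 1 of the 12 alternatives (NF-kB, S100 family, mesenchymal), and 6 inside it came outside. These were immediate-early genes under 7 (percentiles 0.58 to 2.10), TGF-beta response under 3 (98.8 to 99.96), G1/S after neighbour centring (99.02), the unfolded protein response with the median over probe sets (1.19), and as means hypoxia (97.97) and ribosomal proteins (2.06). Low intensity also limits the counts, since folds of dim genes depend on the floor chosen.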

Other observations

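The single genes below were chosen after their values had been seen, as were the lists of cancer-testis genes and of complement and acute-phase genes.

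Of single genes outside the fixed lists, EBI3, a subunit shared by interleukin-27 and interleukin-35, was at least 4.55-fold higher, and TLR3, the receptor for double-stranded RNA, was 2.49-fold higher with both of its probe sets over 2-fold. C3, the central component of complement, was 4.54-fold higher, at 368 in vector cells and 1672 in S100A7 cells. In a list of 30 complement and acute-phase genes, 16 were measured, with C3 the 1 at least 2-fold higher and HPX the 1 lower (2.03-fold). Of the 16, 8 had a log2 ratio above 0, and the median was -0.02, at percentile 62.9. Probe sets listing several genes were outside that list, so it does not show how complement or acute-phase genes read only by such probe sets changed.

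Further single genes stood out. CDA, the cytidine deaminase that recycles pyrimidines, was 5.17-fold higher, and TIE1, a receptor tyrosine kinase best known from endothelium, was 4.27-fold higher. HSPB1, the small heat shock protein Hsp27, was 3.93-fold lower from a high level, at 5649 in vector cells and 1438 in S100A7 cells, and it lies on chromosome 7, whose genes had a median of -0.30. Among the cancer-testis genes, SSX1 was 7.39-fold lower, SSX3 at least 3.47-fold and MAGEA12 at least 3.33-fold lower, each on a probe set shared within its family, and other measured probe sets of SSX1 and SSX3 had log2 ratios up to -0.32 and -0.54. MAGEB2 had a log2 ratio of -0.47.

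The stretches of 40 consecutive measured genes with the most extreme medians lay on chromosome 18 from FHOD3 to ATP8B1 (0.62), on chromosome 6 from CRYBG1 to HDAC2 (0.58), on chromosome 7 from LRCH4 to DPY19L2P2 (-0.60) and on chromosome X from UXT to GPR173 (-0.70). The neighbours of IL11, CXCL8, CXCL1 and IL1A, 60 genes together, had a median log2 ratio of -0.31, opposite to the genes themselves.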
